A study of Mus musculus with 6 samples.

How the data were processed

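ATAC-seq libraries were made from liver of male wild-type mice on a high-fat diet, 3 from C57BL/6J and 3 from 129S1/SvImJ, and sequenced as paired ends, per the labels. The labels give the strain, diet and replicate of each library and do not say whether replicates came from separate animals. The protocol in the labels describes transposition in a mix that contained digitonin, and names the transposed material by an abbreviation it does not explain. An antibody entry naming Esrrg stands in the labels of all 6 libraries and has no role in the ATAC-seq protocol, and the positions alone do not settle whether it was entered in error. The submitters' processing notes name fastp, a read trimmer, Bowtie2, a read aligner, HOMER, a suite that includes a peak caller, and the genome build mm10, without versions or order. The shift of read ends to the transposase site, filters on duplicates and mitochondrial reads, the peak threshold and the rule that combined the libraries are not given in the sources used here. A shift of read ends by a few bases would move interval edges little relative to windows of 1 kb, but an unknown threshold sets how many weak sites entered the list.

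The data were a single list of interval positions deposited by the authors, with 3 columns for chromosome, start and end and no score, read count or signal. Its 120905 intervals were unique, none overlapped another, and 8 pairs touched. Because positions carry no depth, the depth per library is unknown, and no interval's strength could be compared. No column named a strain or library, so the planned comparison of C57BL/6J with 129S1/SvImJ, its replicate block and the fits that leave out a library were not run. No sequence of mm10 was used here, so the planned motif comparison was not run either.

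Genes came from a RefSeq table of the assembly GRCm38.p6, which is the mm10 build, with 49943 genes on the chromosomes used and 21887 protein-coding genes. The table gave gene spans without strand, transcription start sites or exons. In place of the planned promoter windows, both ends of each gene span with 1000 bp to either side were used, and exons and introns were not separated. Start sites farther inside a gene span were therefore not covered. Starts were converted to 1-based positions.

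For genomic features, each interval centre was classed as within 1000 bp of a gene end, elsewhere inside a gene, or between genes, using all genes. Shares were compared with 1000 seeded random placements within the same chromosome, from its first to its last interval or gene, since assembly gaps were not used here. The spread of each share was a jackknife over chromosomes, and p-values were two-sided permutation values adjusted by Benjamini-Hochberg over 3 classes. For 15 gene lists with 287 members, fixed before the data were examined, the share of genes with an interval overlapping an end window by at least 1 bp was compared with that of all other protein-coding genes by a two-sided Fisher's exact test, with exact Clopper-Pearson 95% intervals. The median number of intervals within the gene span and 10000 bp to either side was compared with 10000 random lists matched on gene length in 10 bins, by a two-sided permutation test. Both tests were adjusted by Benjamini-Hochberg over the 15 lists, with a threshold of 0.05. All 287 listed members were found in the gene table, and some genes belong to 2 lists. Intervals per Mb used the same chromosome spans, with exact Poisson 95% intervals.

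Genes and intervals are not replicates, so these p-values describe this list of intervals and not variation between animals. An interval near a gene end may belong to a neighbouring or overlapping gene. Neighbouring members of a list can share intervals or a chromatin state. Random lists were drawn gene by gene, and the exact test counted each gene separately. Both permutation and exact p-values may therefore be too small. Members of multi-copy families are uncertain, since reads from near-identical copies cannot be placed uniquely.

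Genes named in the text followed a rule written before the data were examined. From each list the rule took the 3 genes with the most intervals and up to 2 genes with none, in alphabetical order for ties. It added the 10 protein-coding genes with the most intervals, the 5 widest intervals, taken in order of chromosome name among ties, and Esrrg, Hnf4a, Nr1d1, Arntl and Cyp7a1. Genes named as exceptions to a count, and those named among the additional observations, were chosen after their values were seen. Some genes that these rules would name are not reported here.

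Alternatives were end windows of 500 bp and 5 kb, protein-coding genes only, autosomes and X only, interval centres in place of overlaps, a background of genes with an interval within 100 kb, flanks of 0 and 50 kb, no matching on gene length, and intervals within 500 bp joined, which left 114794. Removal of the narrowest 25% could not be done because 46.2% of intervals share the narrowest width of 201 bp. Added after the data were examined were removal of all intervals of 201 bp, shifts of each interval by 20 to 100 kb, a background without olfactory receptor, vomeronasal receptor and Gm-numbered genes, direct tests between lists, and 12 further lists and 14 gene families.

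Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9. The steps were tested before use, on simulated interval positions and on random or altered gene lists over the real intervals. Uniformly placed intervals gave a ratio at gene ends of 0.997, and a planted share of 20.2% was recovered as 20.2%. Of 200 random lists of 20 genes drawn from 21887, 3.5% had an unadjusted p below 0.05 in the exact test at gene ends and 4% in the permutation test of interval numbers. Of 50 planted lists of 20 genes, 74% were recovered at an adjusted p below 0.05 when 95% of members had an interval at an end, and 96% when members held 3 times the intervals.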

Results

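According to the labels, accessible chromatin was profiled by ATAC-seq, in which a transposase inserts sequencing adapters into open DNA, in livers of male wild-type mice fed a high-fat diet. Of the 6 libraries, 3 came from C57BL/6J and 3 from 129S1/SvImJ, which are inbred mouse strains. The series set out to compare the strains under this diet in the context of hepatic daily rhythms. The labels of all 6 libraries also carry an antibody entry naming Esrrg, although ATAC-seq uses no antibody, so the kind of assay rests on the title and protocol. The deposited list analysed here combined the libraries and held 120905 intervals on 21 chromosomes of mm10, each given by its position alone. Because no interval carried a mark of a strain or a library, the difference between C57BL/6J and 129S1/SvImJ was not measured, and every value below describes the combined list. The depth behind each interval is unknown, since the list gave no read counts, scores or coverage. The intervals were 201 to 401 bp wide (median 203 bp), 55903 of them (46.2%) were exactly 201 bp, and together they covered 26.1 Mb, or 0.965% of the chromosome spans.

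The first question was where the accessible intervals of these livers lay relative to genes. Intervals were concentrated at gene ends. Of 120905 interval centres, 21410 (17.7% ± 0.837, jackknife SE over 21 chromosomes) lay within 1 kb of either end of an annotated gene, against 6.20% ± 0.0717 (SD of 1000 random placements), a ratio of 2.86. Regions between genes held 36.4% ± 1.01 of the centres against 49.5% at random, a ratio of 0.735. The remaining parts of genes held 45.9% ± 0.501 against 44.3%, a ratio of 1.04. For all 3 classes the two-sided permutation p was 0.002 after adjustment, the smallest that 1000 placements can give. The excess inside genes changed direction with the comparison used, because it became a ratio of 0.904 when each interval was compared with positions 20 to 100 kb away instead of anywhere on its chromosome. The excess at gene ends moved between 1.5 with a window of 5 kb and 4.36 with protein-coding genes alone.

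Proximity to a gene end was graded. Within 100 bp of an end the share of intervals was 9 times the random share, from 100 to 250 bp it was 3.41 times, from 500 to 1000 bp 1.6 times, and from 1 to 2 kb 1.14 times. More than 50 kb from any gene end the ratio was 0.701. Intervals wider than 201 bp showed a steeper profile than intervals of exactly 201 bp, with ratios of 13.4 and 3.90 within 100 bp and of 0.478 and 0.961 beyond 50 kb.

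**Figure D1:**
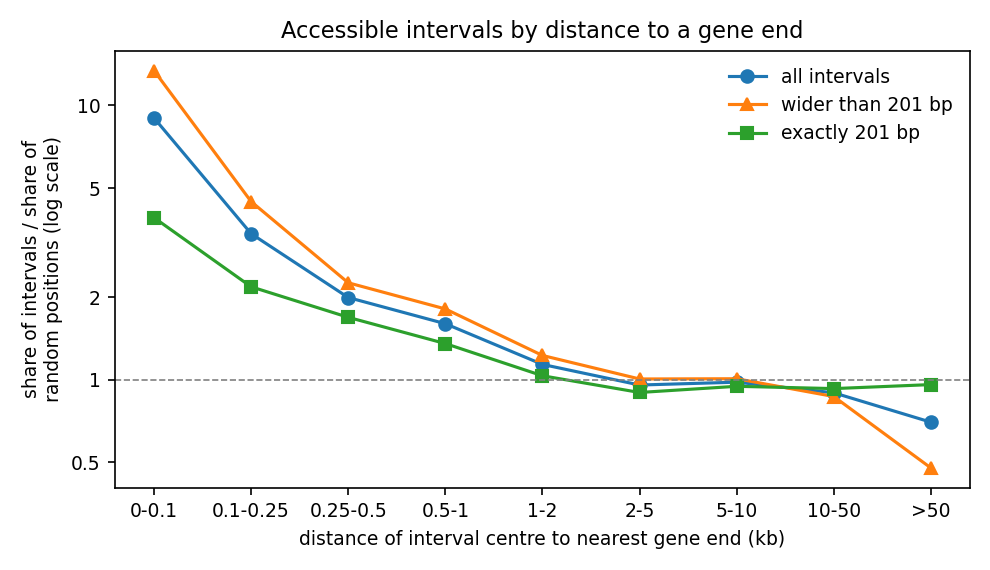
Share of intervals divided by the share of random positions (vertical, log scale) against the distance of the interval centre to the nearest gene end in kb (horizontal), for all intervals and for those wider than and exactly 201 bp. All 3 lines are highest within 0.1 kb, at 9 for all intervals, 13.4 for wider ones and 3.90 for those of 201 bp.

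Genes of hepatic metabolism were marked at their ends more often than other protein-coding genes. Each of the 21 genes of lipogenesis and triglyceride synthesis had an interval overlapping the 1 kb around an end (100%, 95% interval 83.9 to 100), as did each of the 20 genes of glucose and insulin metabolism (100%, 83.2 to 100). In fatty acid oxidation and ketogenesis 21 of 22 genes did (95.5%, 77.2 to 99.9), the exception being Cyp4a14, a fatty acid hydroxylase of a multi-copy family. Among genes of cholesterol and bile acid metabolism the count was 19 of 22 (86.4%, 65.1 to 97.1), without Insig2, Abcg8 and Cyp8b1. Of all 21887 protein-coding genes, 13453 (61.5%) had such an interval, 11335 at 1 end and 2118 at both. Housekeeping genes (85.0%), proteasome subunits (90.0%) and complex I subunits (93.9%) had high shares too. For intervals of all widths together, the metabolic lists were not tested directly against these genes. Their shares therefore do not set hepatic metabolism apart from such genes.

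Two-sided Fisher's exact tests against all other protein-coding genes, adjusted over 15 lists, gave p = 0.000641 for lipogenesis and for glucose metabolism, p = 0.00290 for fatty acid oxidation and p = 0.0332 for cholesterol and bile acids. Without the intervals of exactly 201 bp the share of other genes was 51.7%, and against it the calls for glucose metabolism (65.0%, adjusted p = 0.336 by the same exact test) and fatty acid oxidation (77.3%, adjusted p = 0.0547) were lost, whereas lipogenesis stayed at 100%. The call for cholesterol and bile acids was lost under 4 of the settings tried, with adjusted p between 0.0704 and 0.175.

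Clock genes formed another group with frequent intervals at gene ends. An interval at an end was present in 20 of 22 core clock genes (90.9%, 95% interval 70.8 to 98.9), and Fisher's exact test gave an adjusted p of 0.00951. Housekeeping genes (85.0%), proteasome subunits (90.0%) and complex I subunits (93.9%) had similar shares. Clock genes were not tested directly against them for intervals of all widths, so their share does not set them apart from such genes. The exceptions were Arntl, which encodes the clock activator BMAL1, and Nfil3, a transcriptional repressor. End windows do not cover start sites inside a gene span, so these exceptions do not show that a promoter lacked an interval. Rora, a nuclear receptor that activates Arntl, had the most intervals of the list. It held 52 within its span of 735 kb and 10 kb to either side. Npas2, a partner of BMAL1, had 13, and Arntl had 12 that all lay inside the gene. A median of 6 intervals per clock gene compared with 3.5 in random lists matched for gene length.

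Markers of hepatocytes stood apart from those of immune cells. An interval lay at an end of 20 of 22 hepatocyte genes (90.9%, 95% interval 70.8 to 98.9, adjusted p = 0.00951 by Fisher's exact test), of 8 of 20 macrophage and Kupffer cell genes (40.0%, 19.1 to 63.9) and of 4 of 16 lymphocyte genes (25.0%, 7.27 to 52.4). The lymphocyte share was below that of other genes (adjusted p = 0.00951, exact test), and the macrophage share did not pass the test (adjusted p = 0.104). The lymphocyte share depended on the window, at 6.25% against 56.0% of other genes with 500 bp and 43.8% against 76.8% with 5 kb, and it was below in both. Among the hepatocyte genes, Cps1, the first enzyme of the urea cycle, had 9 intervals, and Ahsg, a secreted plasma glycoprotein, and Arg1, the arginase of the urea cycle, had 5 each. By contrast the macrophage surface gene Adgre1 and the complement gene C1qa had none within 10 kb, nor had the T cell genes Cd3d and Cd8a. Cd68, a lysosomal macrophage protein, had 5, Marco and Spi1 had 4 each, and the lymphocyte genes Ebf1, Ptprc and Cd4 had 13, 8 and 6. These counts were not adjusted for gene length, and Ebf1 spans 390 kb.

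Compared directly with the other lists, the hepatocyte share was higher than the lymphocyte share by 65.9 percentage points (adjusted p = 0.000623 over 8 comparisons, Fisher's exact test), the macrophage share by 50.9 points (adjusted p = 0.00256) and the skeletal muscle share by 53.4 points (adjusted p = 0.00256). It also exceeded the endothelial share by 34.7 points (adjusted p = 0.0421) and the neuronal share by 30.9 points (adjusted p = 0.0474) in the same exact test. Differences from stellate cell, cholangiocyte and housekeeping genes did not pass (adjusted p = 0.289, 0.365 and 0.656, exact test). These direct comparisons were chosen after the data were examined and were run with the 1 kb window only. With a window of 5 kb the hepatocyte and the endothelial share were each 100%. Without the intervals of exactly 201 bp the hepatocyte share was 68.2% against 51.7% of other genes, and the difference was no longer past the threshold (adjusted p = 0.208, exact test).

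None of the other cell type lists passed the test at gene ends. Hepatic stellate cell and fibroblast genes had an interval at an end in 12 of 16 cases (75%, adjusted p = 0.393), cholangiocyte genes in 9 of 12 (75%, adjusted p = 0.452), endothelial genes in 9 of 16 (56.3%, adjusted p = 0.855), neuronal genes in 12 of 20 (60.0%, adjusted p = 1) and skeletal muscle genes in 6 of 16 (37.5%, adjusted p = 0.104), all by Fisher's exact test. Reln, a secreted matrix protein of stellate cells with a gene of 460 kb, had 22 intervals, Lhx2 8 and the collagen gene Col1a2 5. Stab2, a scavenger receptor of sinusoidal endothelium, had 17, and the transcription factor genes Erg and Gata4 had 11 each, although none of these 3 endothelial genes had an interval at an end. With a window of 5 kb the endothelial share became 100% and passed in the other direction (adjusted p = 0.0481, exact test). Among cholangiocyte genes Prom1 had 9 intervals, the chloride channel gene Cftr 8 and Onecut1 5, while the keratin genes Krt19 and Krt7 had none. Syt1, a synaptic vesicle protein gene of 513 kb, had 41, Gad2 8 and Slc17a7 5, while Pvalb and Th had none. The giant sarcomere genes Neb and Ttn had 11 and 8 without any at an end, Casq1 had 5, and the muscle actin gene Acta1 and the myoglobin gene Mb had none. Without the intervals of exactly 201 bp the shares were 37.5% for stellate cell, 41.7% for cholangiocyte, 31.3% for endothelial and 35.0% for neuronal genes, all below the 51.7% of other genes, and the cholangiocyte share was also below at 500 bp (33.3% against 56.0%), with no adjusted p below 0.05. The muscle share was 18.8% with a window of 500 bp and then passed the test (adjusted p = 0.0104, exact test), and it was 62.5% against 76.8% of other genes with 5 kb. The macrophage share passed under 3 settings, at 50.0% with a window of 5 kb (adjusted p = 0.0246, exact test), at 20% without the intervals of exactly 201 bp (adjusted p = 0.0293) and at 40.0% against a background without chemoreceptor and Gm-numbered genes (adjusted p = 0.0330).

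Liver transcription factors and housekeeping genes did not pass the test at gene ends. The counts were 17 of 22 transcription factor and nuclear receptor genes (77.3%, adjusted p = 0.255) and 17 of 20 housekeeping genes (85.0%, adjusted p = 0.0689), by Fisher's exact test. Cebpb, Prox1, Nr3c1 and Esrrb were among the transcription factor genes without an interval there. Nr3c1, the glucocorticoid receptor gene, nevertheless held 14 intervals, 13 of them inside the gene. Nr5a2, an orphan receptor of liver and pancreas, had 26. B2m and Ywhaz had 8 intervals each and the X-linked gene Hprt had 7. Housekeeping genes passed the exact test with a window of 500 bp (85.0%, adjusted p = 0.0241).

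**Figure D2:**
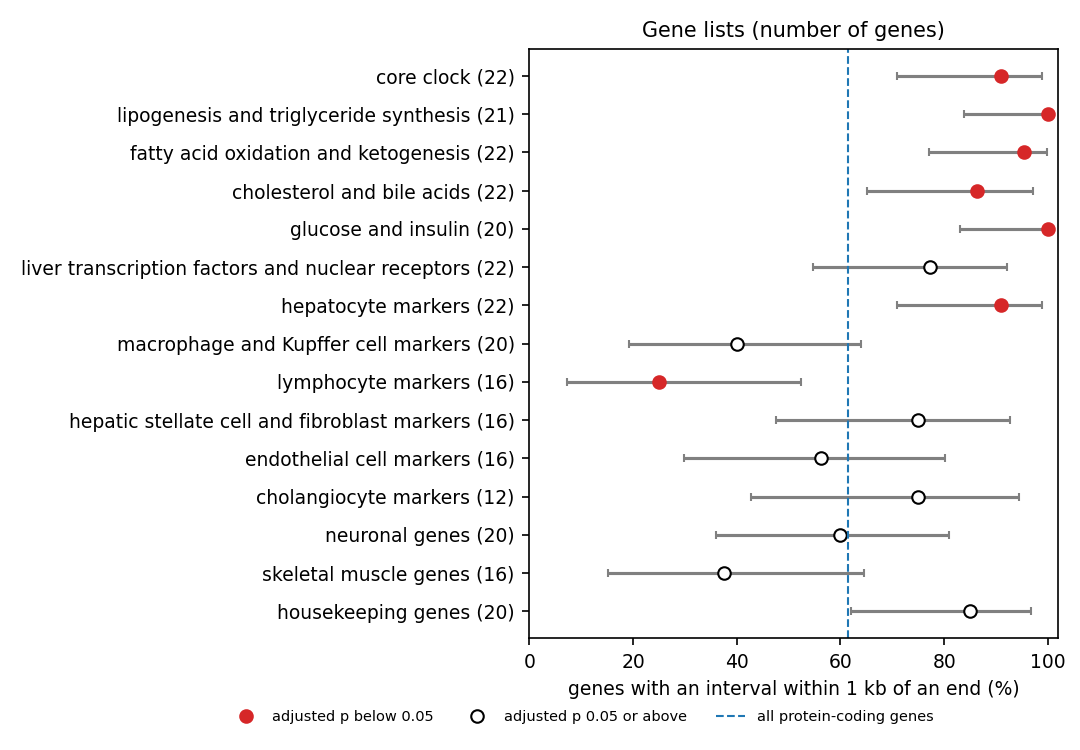
Percentage of genes in each of 15 lists with an interval within 1 kb of an end (horizontal), with 95% exact binomial intervals as bars, the number of genes in brackets and the 61.5% of all protein-coding genes as a dashed line. Filled points mark the 7 lists with adjusted p below 0.05, of which lymphocyte markers (25.0%) lie to the left of the line and 6 lists lie to the right.

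Numbers of intervals in and around genes gave a related picture with other lists in the lead. Protein-coding genes had a median of 3 intervals within the span and 10 kb to either side (quartiles 1 and 5), and 3513 genes (16.1%) had none. Liver transcription factors had a median of 7 against 4 in random lists of the same size and gene length (percentile 99.9), core clock genes 6 against 3.5 (percentile 99.9), glucose genes 6 against 3.5 (percentile 99.8) and fatty acid oxidation genes 5 against 3 (percentile 99.7). These 4 lists passed a two-sided permutation test with 10000 random lists, with p = 0.0285, 0.0285, 0.0340 and 0.0472 after adjustment over 15 lists. No list passed in the other direction at an adjusted p below 0.05 or, with these flanks, at an unadjusted p below 0.05, the lowest medians being 1.5 against 3 for macrophage genes (adjusted p = 0.142) and 1.5 against 3 for skeletal muscle genes (adjusted p = 0.145, permutation test). With flanks of 0 and 50 kb the macrophage medians of 0 against 1 and 5 against 8 had unadjusted permutation p of 0.0334 and 0.0430 (adjusted p = 0.167 and 0.0806). Cholesterol genes with 5 against 3 (adjusted p = 0.0595), housekeeping genes with 4 against 2 (adjusted p = 0.0570), endothelial genes with 6.5 against 4 (adjusted p = 0.0981), hepatocyte genes with 4 against 3 (adjusted p = 0.145) and lipogenesis genes with 6 against 4 (adjusted p = 0.191) did not pass the permutation test. Lymphocyte genes had 2 against 2.5 (adjusted p = 0.747), neuronal genes 2.5 against 3 (adjusted p = 0.412), and stellate cell and cholangiocyte genes 3 against 3 (adjusted p = 1 for both) in the same permutation test. Without flanks the hepatocyte median was 1 against 1. None of the 4 calls held when the 10 kb flanks were left out or when intervals within 500 bp of each other were joined, with adjusted p between 0.0720 and 0.962 in the permutation test, although joined medians were still 6.5 against 3.5 for transcription factors, 5 against 3 for clock, 5 against 3.5 for glucose and 4 against 3 for fatty acid oxidation genes. With flanks of 0 kb these medians were 4.5 against 2, 3 against 2, 3 against 2 and 2 against 1.5 in the same order. Without the intervals of exactly 201 bp the calls for transcription factors (3 against 2.5, adjusted p = 0.824), fatty acid oxidation (3 against 2, adjusted p = 0.394) and glucose genes (4 against 2, adjusted p = 0.0900) were lost in the same permutation test, and clock genes kept theirs (4.5 against 2, adjusted p = 0.00300).

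The metabolic genes with the most intervals included both enzymes and regulators. Elovl6, which elongates long-chain fatty acids, had 20, Me1, a cytosolic source of NADPH, had 17 and Lpin1, a phosphatidate phosphatase, had 16. Ppara, the nuclear receptor that drives fatty acid oxidation, had 10, Bdh1, an enzyme of ketone body metabolism, 9 and Acadm, the medium-chain acyl-CoA dehydrogenase, 7. Cyp7b1, an oxysterol hydroxylase, had 20, Nr1h4, the bile acid receptor gene, 15 and Srebf2, the activator of cholesterol synthesis genes, 8. Ppargc1a, a coactivator of gluconeogenic genes, had 31, the insulin receptor gene Insr 15 and Igf1 13. Ppargc1a spans 662 kb and Igf1 78.8 kb, and these counts were not adjusted for gene length.

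A further 5 genes chosen before the data were examined were followed at single-interval resolution. Esrrg, the estrogen-related receptor gene on chromosome 1 (187608510 to 188214885), had 47 intervals, 46 of them inside the gene, with 1 at each end. Hnf4a, a central hepatocyte transcription factor gene on chromosome 2 (163506811 to 163572907), had 12, of which 1 was centred 33 bp outside its lower-coordinate end and 7 lay inside. Nr1d1, the clock repressor REV-ERBα gene on chromosome 11 (98767932 to 98775377), had 3, including a 205 bp interval centred 96 bp outside its upper-coordinate end and a 335 bp interval at 98783275 to 98783609. Cyp7a1, the rate-limiting enzyme gene of bile acid synthesis on chromosome 4 (6265612 to 6275632), had 6, including a 229 bp interval centred 287 bp outside the upper-coordinate end and a 201 bp interval centred 165 bp inside the lower one. In Arntl on chromosome 7 (113178471 to 113314126) the interval nearest to an end was a 201 bp interval centred 1940 bp inside the lower-coordinate end. Strand and exons were not used here, so an end is either end of the gene span. Start sites inside a span were not located, so the distance in Arntl is not a distance to its promoter.

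**Figure D3:**
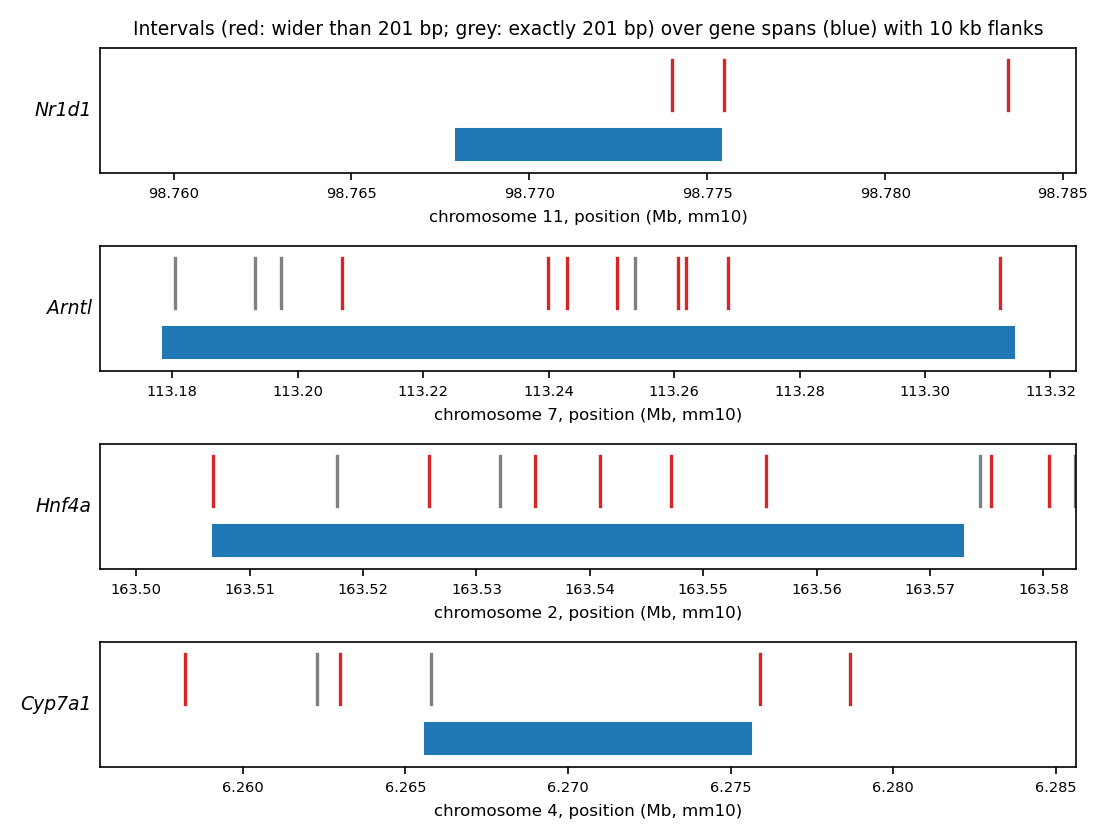
Positions of intervals (vertical ticks, drawn wider than to scale, red for wider than 201 bp and grey for exactly 201 bp) along Nr1d1, Arntl, Hnf4a and Cyp7a1 with 10 kb to either side, in Mb of mm10 (horizontal), with gene spans as blue boxes. Nr1d1 had 3 intervals, Arntl 12, Hnf4a 12 and Cyp7a1 6, and all 12 of Arntl lay inside its span.

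Across all protein-coding genes, the 10 with the most intervals were long genes. Pde4d, a cyclic AMP phosphodiesterase gene of 1302 kb, had 100, followed by Naaladl2 with 91, Ptprd with 90, Lrp1b with 88, Dlg2 with 82, Zbtb20 with 81, Macrod2 with 78, Arhgap26 with 77, and Cntnap2 and Gpc5 with 76 each. Zbtb20, a transcriptional repressor, was the shortest of them at 759 kb and Ptprd the longest at 2271 kb. Gene length and interval number had a Spearman correlation of 0.612 across the 21887 genes, which are not independent replicates. The 5 intervals selected as widest were all 401 bp, the width shared by 10 intervals. Those on chromosome 10 lay inside Rsph14 (74966925 to 74967325) and Specc1l (75221976 to 75222376). The others lay 52645 bp from Glul on chromosome 1 (153962168 to 153962568), 55724 bp from Fign on chromosome 2 (63915584 to 63915984) and 1282314 bp from Edil3 on chromosome 13 (87538958 to 87539358).

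Chromosomes differed in interval density. The 19 autosomes had a median of 47.5 intervals per Mb, from 27.3 on chromosome 19 (95% Poisson interval 26 to 28.7) to 58.4 on chromosome 10 (57.1 to 59.8). Chromosome X had 18.2 per Mb (17.5 to 18.8), 0.382 times the autosomal median, and chromosome 19 had 0.575 times that median. Chromosome Y had 47 intervals, or 0.517 per Mb (0.380 to 0.688). The Poisson intervals cover counting error only, and the animals were male. Without the intervals of exactly 201 bp the ratio for chromosome X was 0.462.

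**Figure D4:**
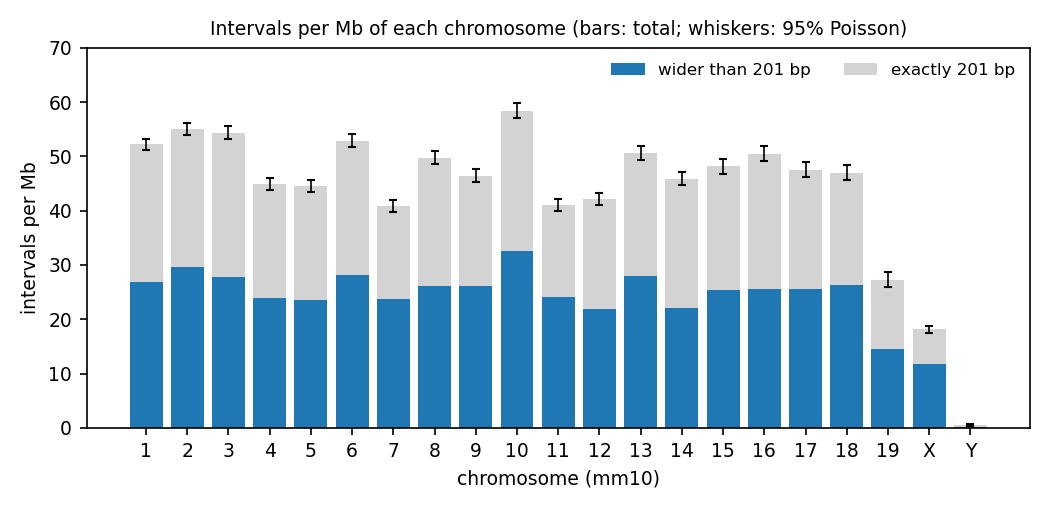
Intervals per Mb (vertical) on each chromosome of mm10 (horizontal), split into intervals wider than 201 bp and of exactly 201 bp, with 95% Poisson intervals of the total as whiskers. Chromosome 10 is highest at 58.4 per Mb, chromosome 19 is the lowest autosome at 27.3, and chromosomes X and Y stand at 18.2 and 0.517.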

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

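Settings that removed the 201 bp intervals, shifted intervals or left chemoreceptor and Gm-numbered genes out of the background were chosen after the data were examined. No paired analysis was possible because the list marks no library. The motif and strain alternatives and removal of the narrowest 25% were not run. Of 214 alternative values, 162 were classed as unchanged. These kept direction and side of the threshold, moved less than their spread or, for counts of lists, changed by at most 1.5-fold. A further 11 changed direction, 9 of them past no threshold under either setting. The excess at gene ends (ratios 1.5 to 4.36) and the deficit between genes (0.610 to 0.870) kept direction and side under every setting run, whereas the excess inside genes reversed to 0.904 with shifted positions. The cause of the changes listed here was not tested. Depth is unknown, so its limit on these values could not be measured.

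At gene ends 6 lists lay above and 1 below other genes at an adjusted p below 0.05, and counts of lists here are of those past it. With a window of 500 bp, 2 lists lay below, cholesterol genes stood at 77.3% and lost their call, and skeletal muscle (18.8%) and housekeeping genes (85.0%) gained one, and cholangiocyte genes turned below other genes (33.3%). With 5 kb, 2 lists lay below, macrophage (50.0%) and stellate cell genes (100%) gained a call, and endothelial genes reversed to 100%. The cholesterol call was also lost against genes with an interval within 100 kb (86.4%). Without the 201 bp intervals (other genes at 51.7%), 2 lists lay above and 2 below, fatty acid oxidation (77.3%), cholesterol (72.7%), glucose (65.0%) and hepatocyte genes (68.2%) lost their calls, macrophage genes (20%) gained one, and stellate cell (37.5%) and cholangiocyte genes (41.7%) turned below other genes. Against a background without chemoreceptor and Gm-numbered genes, 3 lists lay below, cholesterol genes (86.4%) lost and macrophage (40.0%) and muscle genes (37.5%) gained a call.

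For interval numbers, 4 lists passed the permutation test. With flanks of 0 kb, 0 lists lay above at an adjusted p below 0.05 (2 above and 1 below unadjusted), with percentiles of 97.2 for clock, 81.9 for fatty acid oxidation, 95.3 for glucose and 99.7 for liver transcription factor genes. With neighbours joined, 0 lists did (4 unadjusted), with percentiles of 99.2, 96.2, 98.3 and 99.9 in the same order. With flanks of 50 kb, cholesterol (99.6) and housekeeping genes (99.96) gained and glucose genes (98.6) lost a call. Without length matching, lipogenesis (99.9) and endothelial genes (99.8) gained and fatty acid oxidation genes (99.1) lost one. Without the 201 bp intervals, lipogenesis (99.85) and housekeeping genes (99.8) gained, and fatty acid oxidation (96.0), glucose (99.4) and liver transcription factor genes (78.6) lost one. Percentiles changed side for hepatocyte (44.3) and cholangiocyte genes (33.5) with flanks of 0 kb, for cholangiocyte genes with 50 kb (19.9) and without the 201 bp intervals (9.42), and for stellate cell genes with neighbours joined (52.4) and without length matching (53.9), all past no threshold. The ratio of chromosome X to the autosomal median became 0.462 without them.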

Other observations

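The tests in this part were chosen after the values they concern had been seen, except the correlation per Mb of sequence far from gene ends, whose bounds were written before it was computed.

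Glucose and lipogenic genes differed in the kind of interval at their ends. Intervals of exactly 201 bp overlapped an end of 14 of 20 glucose and insulin genes (70%) and of 2 of 21 lipogenesis genes (9.52%), against 18.3% of other genes. Against all other genes the adjusted p over 15 lists was 9.07e-06 for glucose genes, 0.0238 for hepatocyte markers (10 of 22, 45.5%) and 0.506 for lipogenesis genes, by Fisher's exact test. For 7 glucose genes the 201 bp intervals were the sole kind at an end, among them the gluconeogenic enzyme genes Pck1 and G6pc, the regulators Ppargc1a and Foxo1, the glucose transporter gene Slc2a2 and the glucagon receptor gene Gcgr. All 21 lipogenesis genes, among them Fasn, Scd1 and Srebf1, had a wider interval at an end. The direct difference between the lists gave an adjusted p of 0.00702 over the 105 pairs of lists in the exact test, and 3 pairs passed, the others being glucose genes against skeletal muscle (adjusted p = 0.00702) and lymphocyte genes (adjusted p = 0.0267). With windows of 500 bp and 5 kb or with interval centres, the adjusted p for glucose genes against other genes was 0.0412, 0.00617 and 5.03e-05. The glucose list did not stand alone, since hepatocyte markers also passed with 500 bp (adjusted p = 0.0412, exact test) and by centres (adjusted p = 0.0171), and their direct difference from glucose genes did not pass (adjusted p = 0.528 over the 105 pairs). At 5 kb hepatocyte markers (81.8%, adjusted p = 0.000415), fatty acid oxidation (72.7%, adjusted p = 0.00655), endothelial (75%, adjusted p = 0.0118) and liver transcription factor genes (68.2%, adjusted p = 0.0118) also passed the exact test.

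A further 12 lists covered secreted liver proteins, liver zonation and sex bias, and genes of other organs. An interval lay at an end of 20 of 21 complement and coagulation genes (95.2%, adjusted p = 0.00613 over 12 lists, Fisher's exact test), while acute phase (87.5%, adjusted p = 0.0763) and lipid droplet and lipoprotein genes (81.8%, adjusted p = 0.0876) did not pass that test. Interval numbers were above those of length-matched lists for lipid droplet and lipoprotein genes (median 5 against 2, adjusted p = 0.00240, permutation test), acute phase genes (4.5 against 2, adjusted p = 0.00360) and pericentral hepatocyte genes (5.5 against 3, adjusted p = 0.0392), and not for complement and coagulation genes (6 against 4, adjusted p = 0.0582). Periportal (4.5 against 3) and xenobiotic genes (5 against 3.5) did not pass either (adjusted p = 0.153 for both, permutation test). Neighbouring members such as Saa1 and Saa2, Orm1 and Orm2 or Apoc1 and Apoe share flanking sequence, so an interval can be counted for several members. Random lists were drawn gene by gene, so these p-values may be too small. Shares at gene ends were low for exocrine pancreas (14.3%, adjusted p = 0.00485), kidney tubule (21.4%, adjusted p = 0.00923), heart muscle (21.4%, adjusted p = 0.00923) and germ cell genes (25.0%, adjusted p = 0.00923), by Fisher's exact test. Their interval numbers did not pass the permutation test, with medians of 1 against 2 (adjusted p = 0.200), 2.5 against 3.5 (adjusted p = 0.374), 2 against 2.5 and 2 against 2.5 (adjusted p = 0.937 for both). Periportal (78.6%, adjusted p = 0.364), pericentral (71.4%, adjusted p = 0.640), xenobiotic (60.0%, adjusted p = 1), male-biased (72.7%, adjusted p = 0.640) and female-biased liver genes (38.5%, adjusted p = 0.226) did not pass this exact test, and 11 of 12 male-biased genes were in the gene table.

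Gene families spanned a wide range. An interval lay at an end of 131 of 1110 olfactory receptor genes (11.8%), 16 of 353 vomeronasal receptor genes (4.53%), 5 of 42 beta-defensin genes (11.9%), 9 of 56 keratin-associated protein genes (16.1%), 5 of 22 major urinary protein genes (22.7%) and 13 of 39 Hox genes (33.3%). Higher shares were found for complex I subunits (93.9%), proteasome subunits (90.0%), cytosolic ribosomal proteins (87.0%), zinc finger proteins (77.6%) and solute carriers (72.0%). Cytochromes P450 (42.3%) and potassium channels (42.6%) lay below other genes and A-clade serpins at 58.3% did not pass the exact test (adjusted p = 0.835). The other 13 families passed, the largest adjusted p over 14 families being 0.000464 by Fisher's exact test. Family members that lie side by side were counted as separate genes, so these p-values may be too small. Against length-matched lists, median interval numbers were lower for vomeronasal receptors (0 against 1, adjusted p = 0.00699, permutation test), beta-defensins (0 against 2, adjusted p = 0.00699) and major urinary proteins (0 against 2, adjusted p = 0.0168), and higher for ribosomal proteins (3 against 2, adjusted p = 0.00699), in the direction of their shares. For zinc finger proteins they ran the other way (2 against 3, adjusted p = 0.00699, permutation test). Near-identical copies in families such as the major urinary proteins share reads, and this limits what their low shares show.

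Wider intervals lay at gene ends more often than those of exactly 201 bp (23.0% ± 0.923 against 11.6% ± 0.672, jackknife SE), with a ratio by centres of 1.98 (95% interval 1.87 to 2.09) that was above 1 on 21 of 21 chromosomes (p = 1e-05, sign-flip permutation test, the smallest it can give). Among wider intervals the share did not rise steadily with width. It was 23.2% at 202 to 211 bp and 21.05% at 227 to 251 bp, a difference of -2.19 points ± 0.317 (jackknife SE). From 252 to 301 bp it was 25.3%, and from 302 bp on it was 29.0%. The bins compared were chosen after their shares were seen, and the widest bins had the highest shares. A part for width therefore stays open. The widest interval was 401 bp, exactly the widest union of a pair of 201 bp calls that overlap by 1 bp, and the list opened with 53682 lines of 201 bp, followed by 67223 lines of which 3.30% were 201 bp, which is consistent with a combination of 2 lists of equal-width calls, in which most 201 bp intervals may have been called in 1 list only. The lists may have been the strains, but calls made in 1 strain only cannot be told apart from weak sites missed by chance, since 0 columns mark a strain. A strain difference therefore stays open and untested, also for the glucose genes.

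Gene-dense autosomes held fewer intervals far from gene ends. Far means over 10 kb from an end of a protein-coding gene, and it includes positions inside long genes. Protein-coding genes per Mb and such intervals per Mb had a Pearson r of -0.75 and a Spearman rho of -0.62 (adjusted p = 0.000840 and 0.0160 over 3 relations, permutation tests, 19 autosomes). Less sequence far from gene ends was the technical explanation weighed, and per Mb of such sequence r was -0.62 (95% interval -0.84 to -0.23, adjusted p = 0.00682) and rho -0.44 (adjusted p = 0.0923). The value passed the bound of -0.5 written beforehand as evidence against this explanation, but its interval reaches across that bound, a condition applied after the value was seen, so this explanation stays open. Without chromosomes 7 and 11, the farthest from the median gene density, r was -0.51, and without chromosome 19 it was -0.57. Over all intervals r was -0.52 (adjusted p = 0.0219) and rho -0.37 (adjusted p = 0.115), and no biological explanation was tested.

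Chromosome X held fewer intervals per Mb than every autosome. A low number of genes was argued against as the whole cause, since 51% of its 832 protein-coding genes outside the chemoreceptor and Gm-numbered groups had an interval at an end (95% interval 47.5 to 54.4), below the 63.6% (61.1 to 66.0) of chromosome 7, the lowest autosome. Chromosomes X and 12 also had the same density of 5.66 protein-coding genes per Mb, and chromosome 12 held 42.1 intervals per Mb. Far from the ends of protein-coding genes, chromosome X held 13.5 intervals per Mb of such sequence, against 17.5 on chromosome 19, the lowest autosome there. The single X copy in males may have lowered coverage and with it the number of calls, and the density ratio of 0.382 cannot be told apart from a difference in chromatin because no coverage was used here. Females were not analysed here.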
